A study of Vitis vinifera with 12 samples.

How the data were processed

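Small RNA was sequenced from young leaves and fruit peels of 3 grape (Vitis vinifera) cultivars, Bangalore Blue, Red Globe and Dilkhush, with 2 replicates of each of the 6 combinations, which makes 12 libraries. Per the labels' protocols, total RNA was extracted with a plant RNA column kit, with small changes to the manufacturer's procedure, and was fractionated by size. The deposited files hold raw read counts, 1 file per library, with each distinct sequence of 16 to 35 nt beside the number of reads that carried it. Sequences seen once were kept in the files, and under 0.04% of reads in each library contained an undetermined base. The sequencer, the adapter removal and any quality filter are not given in the sources used here. The groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate plants, so the p-values measure only the spread between these samples, which may be technical.

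The libraries held 2534597 to 5996036 reads, 42450700 in all to 6 digits. Reads were not marked with molecular identifiers, so intervals and detection floors cover counting error only. A floor of 3 reads corresponded to 0.5003 to 1.18 RPM (reads scaled to the total of the library), depending on the library. The 2 replicates of every group differed by more than sampling noise, with chi-square values per degree of freedom of 1.75 to 20.4 over miRNA families, so no pair was treated as copies of a single library.

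Sequences of 20 to 24 nt were assigned to a miRNA family when their first 18 bases equalled those of a mature sequence in a list of 78 matures from 40 conserved families, written from general knowledge of plant miRNAs before the data were examined. Counts were summed over the sequences of a family. Families were grouped in advance into lists linked to MYB factors, phase change, auxin, development, copper, nutrients, the silencing machinery and NLR resistance genes, with the rest as other families. Of the 2360273 distinct sequences of 20 to 24 nt, 78729 had at least 10 reads over all libraries. Members of a family whose mature sequences are near-identical, and the loci behind them, cannot be separated at this level.

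Family counts and sequence counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, glmQLFit and glmQLFTest) with 1 coefficient per group over all 12 libraries, so that all groups shared the estimate of spread. Offsets were the total reads of the library times TMM factors from the matrix of distinct sequences. The 35 families with at least 10 reads in at least 2 libraries and the 18127 sequences kept by filterByExpr were tested. Adjusted p-values are Benjamini-Hochberg over the families or sequences of a comparison, with a threshold of 0.05. CPM are the same unit with the library size after TMM. The comparisons were peel against leaf over the 3 cultivars, each pair of cultivars within peel and within leaf, and, for families, the 3 interaction terms that compare a cultivar difference in peel with that in leaf. Where a group in a comparison of peel and leaf or of cultivars had 3 reads or fewer, the pooled reads of each side gave a ratio with a 95% exact counting interval, or, against 0 reads, a lower bound computed with 3 reads over the group. Groups just above that number got no such interval, and their fitted folds are uncertain as well.

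The shares of 21-nt and 24-nt reads among reads of 18 to 30 nt were compared between tissues with 2-sided exact permutation tests that permuted tissue within each cultivar (216 arrangements, smallest possible p 0.00926). Pairs of cultivars with 2 libraries each were not tested for shares, since no exact test of that size can pass 0.05. Exact matches to short lists of ribosomal RNA, small nuclear RNA, transfer RNA, animal miRNA and hop stunt viroid sequence were counted in each library as signs of RNA breakdown, of other organisms or of infection.

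The families named in the text were chosen by a rule fixed in advance: miR828 and miR858 in every comparison, then in each direction up to 12 families with the largest absolute log2 fold change among those past the threshold whose replicates did not overlap between the groups. Of distinct sequences, up to 3 per direction with a mean of at least 10 CPM were selected in the same way. Sequences outside the listed families are described without their bases, because their origin was not assigned.

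The test procedure was run on simulated counts with the real library sizes and the mean of each feature over all libraries. All features shared 1 dispersion (0.0278 for sequences, 0.00802 for families), and the offsets were taken as known. At each fold change 100 sequences or 5 families were changed. In the data the spread differs between features and far more are called, so the simulation does not give the error rate of the real calls. For peel against leaf, 49% of the sequences changed 2-fold and 92% of those changed 4-fold were recovered, and 4 of 17927 unchanged sequences were called. For Bangalore Blue against Dilkhush in peel the recovered shares were 18% and 72%, with 2 unchanged sequences called. Among families, all those changed 2-fold and 4-fold were recovered for peel against leaf with 0 of 25 unchanged families called, and 80% and 100% for Bangalore Blue against Dilkhush in peel with 1 of 25 called.

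The alternatives fixed in advance were total reads without TMM, scaling to miRNA reads, DESeq2 1.42.0 with its own size factors, other filters, exact mature sequences and 1 mismatch. The replicate number as a block, only the libraries compared, other size classes and each library left out in turn were also planned. Scaling to miRNA reads means the reads in the families times TMM factors computed among the families. Such factors assume that most families do not change, so a shift shared by most families is largely removed on that scale. Scaling to 24-nt reads, shares without miR166 and tests without sequences that shared 15 bases with circular RNAs were added after the data were seen. Circular sequences were searched among reads of at least 18 nt seen at least 2 times in a cultivar. Overlaps of 15 bases were extended until a path closed on itself at 250 to 450 nt. Paths started only from sequences missing from a cultivar (at most 3 reads there and at least 100 elsewhere). Circles reached only from shared sequences could therefore not be found. No genome was used here, so small RNAs at MYB genes and the alternative restricted to sequences of the reference genome were not analysed here, and no genome positions are given. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.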

Results

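Small RNA populations were profiled in young leaves and fruit peels of 3 grape cultivars chosen for their different anthocyanin levels. The series title places miRNAs and repressors of the MYB family, transcription factors that control anthocyanin genes, at the centre of the study. From general knowledge of the cultivars, Bangalore Blue berries are dark, Red Globe berries are red and Dilkhush berries are pale. Each of the 6 groups had 2 libraries. Bangalore Blue leaf libraries held 2879539 and 3736998 reads, Red Globe leaf 2534597 and 3050354, and Dilkhush leaf 2557358 and 3860875. Bangalore Blue peel libraries held 3054540 and 4438658 reads, Red Globe peel 4233235 and 2951279, and Dilkhush peel 3157230 and 5996036.

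The most abundant listed miRNA was miR166, which targets class III HD-ZIP factors of leaf and vascular patterning. Its sequence TCGGACCAGGCTTCATTCCCC was the most frequent sequence in Bangalore Blue leaf and in all peel libraries, with 7.02% to 20.03% of reads. A 23-nt sequence of no listed family led the Red Globe and Dilkhush leaf libraries with 10.3% to 13.6% of reads. Reads in the listed families made up 26.0% and 22.7% of the Bangalore Blue leaf libraries, 7.65% and 9.08% of Red Globe leaf and 7.46% and 6.71% of Dilkhush leaf. In peel they made up 12.6% and 12.5% of Bangalore Blue, 14.6% and 15.7% of Red Globe and 9.13% and 8.03% of Dilkhush libraries. Because these shares differed between groups, the direction of a moderate change depended on the reference chosen, and each direction below is given with the scalings that turned it.

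Fragments of other RNAs also varied with group. Reads matching 5.8S ribosomal RNA made up 0.880% ± 0.007 (SD, n = 2) of Bangalore Blue peel and 0.299% ± 0.027 of its leaf, 0.514% ± 0.004 of Red Globe peel and 0.694% ± 0.047 of its leaf, and 0.553% ± 0.041 of Dilkhush peel and 0.373% ± 0.017 of its leaf. The 5' end of tRNA-Ala was more frequent in the peel of each cultivar, at 0.196% against 0.086% in Bangalore Blue, 0.131% against 0.049% in Red Globe and 0.3003% against 0.033% in Dilkhush. Group means were at most 0.008% for tRNA-Gly, 0.001% for tRNA-Asp and 0.004% for U6 snRNA. Animal miR-122 had 0 reads in all 12 libraries, which allows at most 0.5003 to 1.18 RPM. Animal let-7 had 2 to 318 reads and animal miR-21 had 2 to 367 reads per library. Reads matching hop stunt viroid, a circular plant pathogen, made up 0.518% ± 0.003 of Bangalore Blue peel, 0.184% ± 0.012 of Bangalore Blue leaf, 0.167% ± 0.015 of Dilkhush peel, 0.049% ± 0.004 of Dilkhush leaf, 0.093% ± 0.004 of Red Globe peel and 0.123% ± 0.014 of Red Globe leaf.

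The first question was whether the size classes differed between tissues. In plants, 21-nt RNAs include most miRNAs and 24-nt RNAs guide DNA methylation. The 21-nt class made up 32.9% ± 3.51 of reads of 18 to 30 nt in peel and 32.0% ± 10.1 in leaf (SD, n = 6 each). The difference of 0.98 percentage points lay within the spread (2-sided exact permutation test within cultivars, p = 0.769). The wide leaf spread came from the cultivars, with 44.3% ± 3.47 in Bangalore Blue, 28.7% ± 1.90 in Red Globe and 22.9% ± 1.02 in Dilkhush (n = 2 each). In peel the class made up 32.1% ± 0.89, 36.9% ± 2.17 and 29.9% ± 2.25 in the same order. Peel was thus lower than leaf in Bangalore Blue and higher in the other cultivars, and these differences offset each other in the mean. The 24-nt class made up 11.1% ± 2.53 of peel reads and 9.08% ± 1.24 of leaf reads, a difference of 1.98 points (exact permutation p = 0.204). Dilkhush had 14.1% ± 0.45 of 24-nt reads in peel and 7.85% ± 0.16 in leaf, whereas Red Globe had 8.57% ± 0.77 and 9.003% ± 0.205. As a share of reads of 20 to 24 nt the 24-nt difference was 4.01 points (exact permutation p = 0.0463), and over distinct sequences it was -4.88 points (exact permutation p = 0.120).

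**Figure D1:**
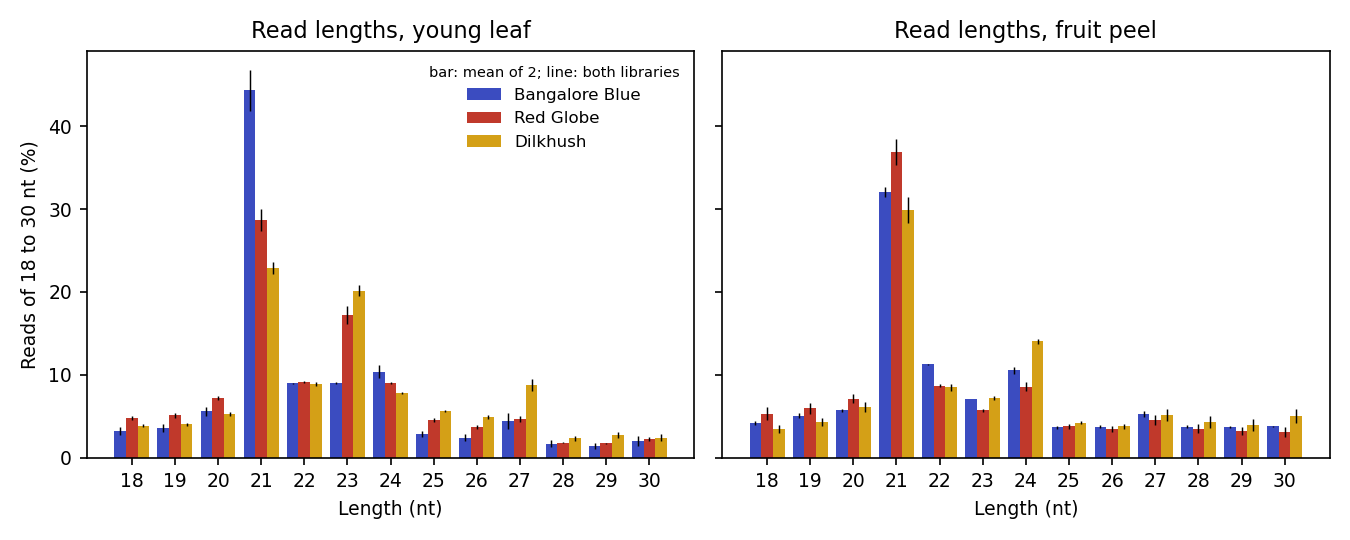
Percentage of reads of 18 to 30 nt (vertical axis) at each length in nt (horizontal axis) in young leaf and fruit peel. Bars are the mean of 2 libraries and lines span both. The 21-nt class ranged from 22.9% in Dilkhush leaf to 44.3% in Bangalore Blue leaf, and the 24-nt class was 14.1% in Dilkhush peel.

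Peel against leaf asked which miRNAs mark the tissue in which berry colour forms. Among the largest falls in peel were families that target auxin response factors and regulators of organ growth. The tasiR-ARF RNAs, which silence auxin response factors, gave 11 reads in all peel libraries and 2566 in leaf, a ratio of 476-fold (95% counting interval 265 to 954), with 0 reads in Red Globe peel. For miR160, which targets other auxin response factors, peel had 23 reads, 1 of them in Bangalore Blue, against 2274 in leaf (202-fold lower, counting interval 134 to 319). The NAC-targeting miR164 had 14 against 684 reads (99.6-fold lower, 59.0 to 183), and miR394, which targets an F-box gene, had 8 against 597 (152-fold lower, 76.7 to 354). The fitted folds, which weigh the cultivars equally, were 191, 95.1 and 93.4 for miR160, miR164 and miR394, and the fitted log2 value moved from -7.57 to -8.25 for miR160 without Bangalore Blue peel replicate 2 and from -6.55 to -7.59 and -7.46 for miR394 without peel replicate 1 of Red Globe and of Dilkhush. The growth-regulating factor regulator miR396 was 18.9-fold lower (log2 fold change -4.24 ± 0.10, SE). In the opposite direction, the grapevine miR3624 rose 24.1-fold in peel (4.59 ± 0.16), miR393, which targets auxin receptors, 6.86-fold (2.78 ± 0.14), and miR403, which targets AGO2, 2.61-fold (1.38 ± 0.09). All of these directions held under each scaling tried.

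The MYB-targeting miR858 was higher in peel than in leaf of every cultivar, 1.69-fold over the 3 cultivars (log2 fold change 0.76 ± 0.11, edgeR quasi-likelihood test, adjusted p = 5.4e-10). Its levels were 112 ± 15.3 CPM in Bangalore Blue peel against 59.5 ± 12.7 in leaf, 31.2 ± 4.22 against 21.7 ± 3.11 in Red Globe and 41.1 ± 7.76 against 22.8 ± 0.52 in Dilkhush (SD, n = 2). Its main sequence, TTCGTTGTCTGTTCGACCTTG, carried 96.9% of the family's reads. Scaled to the reads in miRNA families, the difference was 2.02. The related regulator miR828 gave 1 read in all 12 libraries, so it could not be compared at this depth. The remaining MYB-linked family, miR159, which targets GAMYB factors, was lower in peel with -0.97, a direction that turned when scaled to miRNA reads.

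By list, 4 of 5 auxin families fell and 1 rose in peel, and the other fallers were miR390 at -3.51 ± 0.19 and miR167 at -2.38 ± 0.11. Of 8 development families 5 fell and 1 rose, with miR171 at -2.11 ± 0.20. Among these, the fall of miR166 turned to a rise without TMM and when scaled to miRNA reads. Both called nutrient families fell (2 of 3), with miR395, which targets sulphate assimilation, at -2.82 ± 0.23, whereas the fall of miR399 turned when scaled to miRNA reads. The NLR-targeting miR482 fell 3.999-fold (-1.9998 ± 0.07). Of 3 phase-change families only miR156, which targets SPL factors, fell (-1.20 ± 0.14), and it stood at 0.06 when scaled to miRNA reads. The copper list had 1 higher and 1 lower of 3, miR398 and miR408, and the fall of miR408 turned when scaled to miRNA reads. Bangalore Blue did not share the rise of miR398, at 382 CPM in peel and 453 in leaf. The silencing list had 1 higher (miR403) and 2 lower of 3, and the falls of miR162 and miR168 turned when scaled to miRNA reads and without TMM, that of miR162 also when scaled to 24-nt reads. Of the 7 other families 1 rose and 3 fell, among them miR529 with 2 peel and 87 leaf reads (88.7-fold, counting interval 23.8 to 744), and miR479 and miR3634, whose falls turned when scaled to miRNA reads. The counts adjusted over the list alone were the same.

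In all, 6 families were higher and 20 lower in peel of 35 tested. The split was 10 and 13 without TMM, 18 and 11 when scaled to miRNA reads and 7 and 14 when scaled to 24-nt reads, since these moved the median family change of -0.61 by 0.71, 1.25 and 0.54. Of the families that turned, miR159, miR162, miR166, miR168, miR408 and miR3634 passed the threshold in the opposite direction when scaled to miRNA reads, as did miR162 without TMM and when scaled to 24-nt reads. The calls average the cultivars, which did not always share a direction. In Bangalore Blue peel miR398 was lower and miR168 higher than in leaf (178 against 168 CPM for miR168). Red Globe peel had more miR399 (1.92 against 1.35 CPM) and Dilkhush peel more miR479 (2.51 against 1.55), both at few reads. The fall of miR3634 came mainly from Bangalore Blue (4212 against 18696 CPM), with 2616 against 2684 in Red Globe and 4197 against 4281 in Dilkhush.

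**Figure D2:**
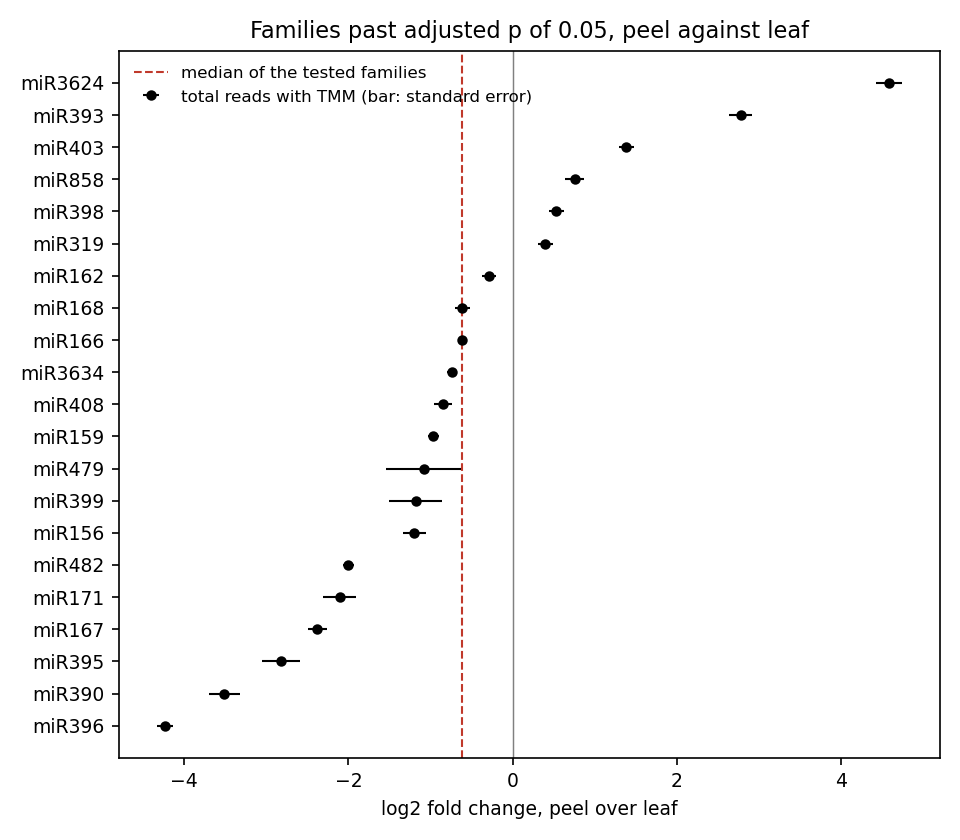
Log2 fold change of peel over leaf (horizontal axis) with its standard error for the families past the threshold (vertical axis), leaving out miR160, miR164, miR394, miR529 and tasiR-ARF, which had a group with 3 reads or fewer. The dashed line is the median of all 35 tested families, -0.61. Values run from -4.24 for miR396 to 4.59 for miR3624, and those of miR156, miR159, miR162, miR166, miR168, miR399, miR408, miR479 and miR3634 change sign when scaled to miRNA reads.

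Bangalore Blue against Dilkhush in peel set the darkest cultivar against the palest. In Bangalore Blue peel miR858 was 2.74-fold more abundant (log2 fold change 1.46 ± 0.16, edgeR quasi-likelihood test, adjusted p = 1.2e-15), with 112 ± 15.3 against 41.1 ± 7.76 CPM and no overlap of replicates. The AGO2 regulator miR403 was 6.47-fold higher (2.69 ± 0.15), at 1070 ± 258 against 165 ± 27.6 CPM. The copper-responsive miR398, which targets superoxide dismutases, was 4.57-fold higher (2.19 ± 0.15). The rarer miR390, which starts tasiR-ARF formation, was 10.6-fold higher (3.41 ± 0.43), with 28 and 40 reads against 3 and 4. In the other direction miR395 was 3.71-fold lower (-1.89 ± 0.30) and miR169, which targets NF-YA factors, was 5.96-fold lower (-2.58 ± 0.72), with 2 and 2 reads against 12 and 17.

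All 3 phase-change families, all 3 silencing families, all 3 copper families and both tested MYB-linked families were called higher in Bangalore Blue peel. The phase-change list included miR535 at 1.84 ± 0.29 and miR172, which targets AP2-like factors, at 1.06 ± 0.42, a call lost when scaled to miRNA reads (0.74) and with exact mature sequences (0.97). In the copper list miR397, which targets laccases, stood at 1.65 ± 0.76, and most alternatives ended its call: scaling to miRNA reads (1.36), DESeq2 (1.79), exact mature sequences (1.65), 1 mismatch (1.44) and the use of only the libraries compared (1.66). Of 8 development families 4 were higher and 1 lower, with miR396 at 1.85 ± 0.17 and miR319 at 1.39 ± 0.15. The rare miR530 had 56 reads in Bangalore Blue peel and 2 in Dilkhush peel, a ratio of 32.1-fold (counting interval 8.47 to 271). Of 5 auxin families 2 were higher and 1 lower, miR160 with 1 against 13 reads (11.4-fold lower, 1.71 to 482). Of 3 nutrient families 2 were lower, miR395 and miR2111, the latter with 3 against 22 reads (6.404-fold lower, 1.92 to 33.4). The NLR-targeting miR482 was higher, which turned when scaled to miRNA reads. Among the 7 other families 2 were higher, miR3624 at 1.62 ± 0.16 and miR477 at 1.81 ± 0.47, and miR479 was lower at -1.41 ± 0.64, a direction that turned to 0.25 when 1 mismatch was allowed and a call lost without TMM (-1.31), with DESeq2 (-1.40) and when scaled to 24-nt reads (-0.95). Adjusted over the list alone the counts were the same, except that miR479 was not called.

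The total was 20 families higher and 5 lower of 35, or 14 and 7 when scaled to miRNA reads, which moved the median of 0.72 by -0.30 (24-nt scaling moved it by 0.43). Without Bangalore Blue peel replicate 1 the calls of miR172 (0.95), miR397 (1.65) and miR479 (-1.01) were lost, without its replicate 2 those of miR397 (1.64) and miR2111 (-1.92), without Dilkhush peel replicate 1 that of miR397 (0.97), and without its replicate 2 those of miR160 (-2.43), miR172 (0.81) and miR479 (-0.80). Without Dilkhush peel replicate 2 miR397 stood at 5.73, without Bangalore Blue peel replicate 2 miR479 stood at -2.26, and all Dilkhush reads of miR530 came from replicate 2. Of the families with few reads, miR530 was fitted at 4.17 and 7.44 without Dilkhush replicates 1 and 2, and without Bangalore Blue replicates 1 and 2 miR160 was fitted at -2.53 and -5.19, and without the first of them miR2111 at -3.28.

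Red Globe against Dilkhush in peel compared the red with the pale cultivar. Here the direction of miR858 depended on the scaling: it was lower in Red Globe by -0.39 ± 0.18 (edgeR quasi-likelihood test, adjusted p = 0.0411), which turned to 0.18 when scaled to miRNA reads and to 0.62, past the threshold in the opposite direction, when scaled to 24-nt reads. The copper families were higher in Red Globe, miR398 7.20-fold (2.85 ± 0.15), miR408, which targets plantacyanins, 2.88-fold (1.53 ± 0.18) and miR397 5.86-fold (2.55 ± 0.65, but 1.87 without Dilkhush peel replicate 1 and 6.63 without its replicate 2). The grapevine families miR3627 and miR3624 were 8.64-fold (3.11 ± 0.63) and 2.98-fold (1.57 ± 0.16) higher. In Red Globe peel miR395 was 9.08-fold lower (-3.18 ± 0.35), miR172 5.66-fold lower (-2.50 ± 0.71) and miR156 3.89-fold lower (-1.96 ± 0.27). For miR172 the Red Globe peel libraries held 3 and 1 reads against 11 and 13 in Dilkhush peel.

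All 3 copper families were thus higher, whereas all 3 silencing families were lower. Of the latter miR162, which targets DCL1, stood at -0.84 ± 0.14, and each of the 3 turned when scaled to 24-nt reads, miR403 also when scaled to miRNA reads and without TMM. Both MYB-linked families were lower, and miR159 (-0.90 ± 0.12) turned to 0.10 when scaled to 24-nt reads. Of 3 phase-change families 2 were lower. Of 8 development families 1 was higher, miR166 at 0.56 ± 0.05, and 3 were lower: miR171 at -1.80 ± 0.39, miR396 at -1.12 ± 0.20 and miR319 at -0.99 ± 0.15, which stood at 0.01 when scaled to 24-nt reads. Of 5 auxin families miR390 was higher (1.54 ± 0.56) and 2 were lower, tasiR-ARF with 0 against 5 reads (at least 1.68-fold lower) and miR393, which turned when scaled to miRNA or 24-nt reads. Of 3 nutrient families 2 were lower, with miR399 at -1.23 ± 0.38. Of 7 other families 2 were higher and 3 lower: miR477 with 3 against 17 reads (5.71-fold, 1.65 to 30.4), miR479 at -1.95 ± 0.67 and miR3634, which turned when scaled to 24-nt reads. The NLR-targeting miR482 did not pass. The counts adjusted over the list alone were the same.

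In all 7 families were higher and 17 lower in Red Globe. The split was 8 and 11 without TMM, 11 and 8 when scaled to miRNA reads and 15 and 2 when scaled to 24-nt reads, with the median of -0.39 moved by 0.32, 0.57 and 1.01. Scaled to 24-nt reads, miR403 also passed in the opposite direction. The miR858 call was lost with DESeq2 (-0.33), without TMM (-0.07), with exact mature sequences (-0.41), with only the libraries compared (-0.39), without Dilkhush peel replicate 1 (-0.20) and without Red Globe peel replicate 1 (-0.25) or 2 (-0.53), and single libraries also ended those of miR390 (0.75 without Red Globe replicate 2, 1.38 without Dilkhush replicate 2), miR477 (-1.78 and -2.25 without Red Globe replicate 1 and Dilkhush replicate 2), miR479 (-1.93 and -1.34 without the same libraries) and tasiR-ARF (without Dilkhush replicate 2 or either Red Globe library). Without Red Globe peel replicate 1 miR390 stood at 2.17 and miR172 at -3.17, and without its replicate 2 miR477 was fitted at -3.06. Scaling to 24-nt reads ended the calls of tasiR-ARF, miR171 (-0.82), miR172 (-1.55), miR396 (-0.11), miR399 (-0.22), miR477 (-1.43) and miR479 (-0.95), and scaling to miRNA reads those of miR162 (-0.26), miR399 (-0.65), miR477 (-1.87) and miR479 (-1.39). The calls of miR399 (-0.88) without TMM, of miR172 (-1.95) and miR396 (-0.75) with exact mature sequences and of miR390 (1.55) with only the libraries compared were also lost.

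Bangalore Blue against Red Globe in peel compared the dark with the red cultivar. In Bangalore Blue peel miR858 was 3.596-fold higher (1.85 ± 0.17, edgeR quasi-likelihood test, adjusted p = 6.0e-22), and 0.96 when scaled to miRNA reads. The families miR403, miR396 and miR156 were 8.09-fold (3.02 ± 0.15), 7.88-fold (2.98 ± 0.18) and 7.35-fold (2.88 ± 0.25) higher. The copper families went the other way, miR408 at -0.78 ± 0.17 and miR398 at -0.66 ± 0.14. Also lower, by 10.2-fold, was miR169 (-3.35 ± 0.64), with 2 and 2 reads against 23 and 27.

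All 3 phase-change families, all 3 silencing families and both MYB-linked families were higher in Bangalore Blue, with miR172 at 3.56 ± 0.62, miR535 at 2.03 ± 0.29 and miR162 at 1.75 ± 0.15. Of 8 development families 4 were higher and 1 lower, with miR530 at 2.97 ± 0.58 and miR319 at 2.38 ± 0.15. Of 5 auxin families 3 were higher, with miR390 at 1.87 ± 0.34 and tasiR-ARF with 6 against 0 reads (at least 2.31-fold), and miR160 was lower with 1 against 9 reads (7.80-fold, 1.08 to 342). Of 3 nutrient families 2 were higher and 1 lower, miR2111 with 3 against 36 reads (10.4-fold, 3.29 to 52.8). Of 7 other families 2 were higher and 1 lower: miR477 with 53 against 3 reads (20.4-fold, 6.60 to 102), miR3634, which turned when scaled to miRNA reads, and miR3627 at -1.71 ± 0.53. The NLR-targeting miR482 was higher, which turned when scaled to miRNA or 24-nt reads. Of the copper list 2 of 3 were lower. The counts adjusted over the list alone were the same.

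In all 20 families were higher and 6 lower, or 16 and 8 without TMM, 15 and 12 when scaled to miRNA reads and 15 and 10 when scaled to 24-nt reads, with the median of 1.18 moved by -0.26, -0.89 and -0.56, and miR482 passed in the opposite direction when scaled to miRNA reads. The call of miR160 was lost without Bangalore Blue peel replicate 1 (-2.01), with DESeq2 (-2.99) and with exact mature sequences (-2.47), while its fitted value was -4.68 without Bangalore Blue peel replicate 2, that of miR172 with exact mature sequences (2.92), that of miR3627 without Bangalore Blue peel replicate 2 (-1.23), and miR390 ranged from 1.24 without Red Globe peel replicate 1 to 2.66 without its replicate 2, while miR172 reached 4.23 without Red Globe peel replicate 1. With single libraries left out the fitted values ranged from 3.58 to 4.87 for miR477 and from -2.61 to -3.96 for miR2111.

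**Figure D3:**
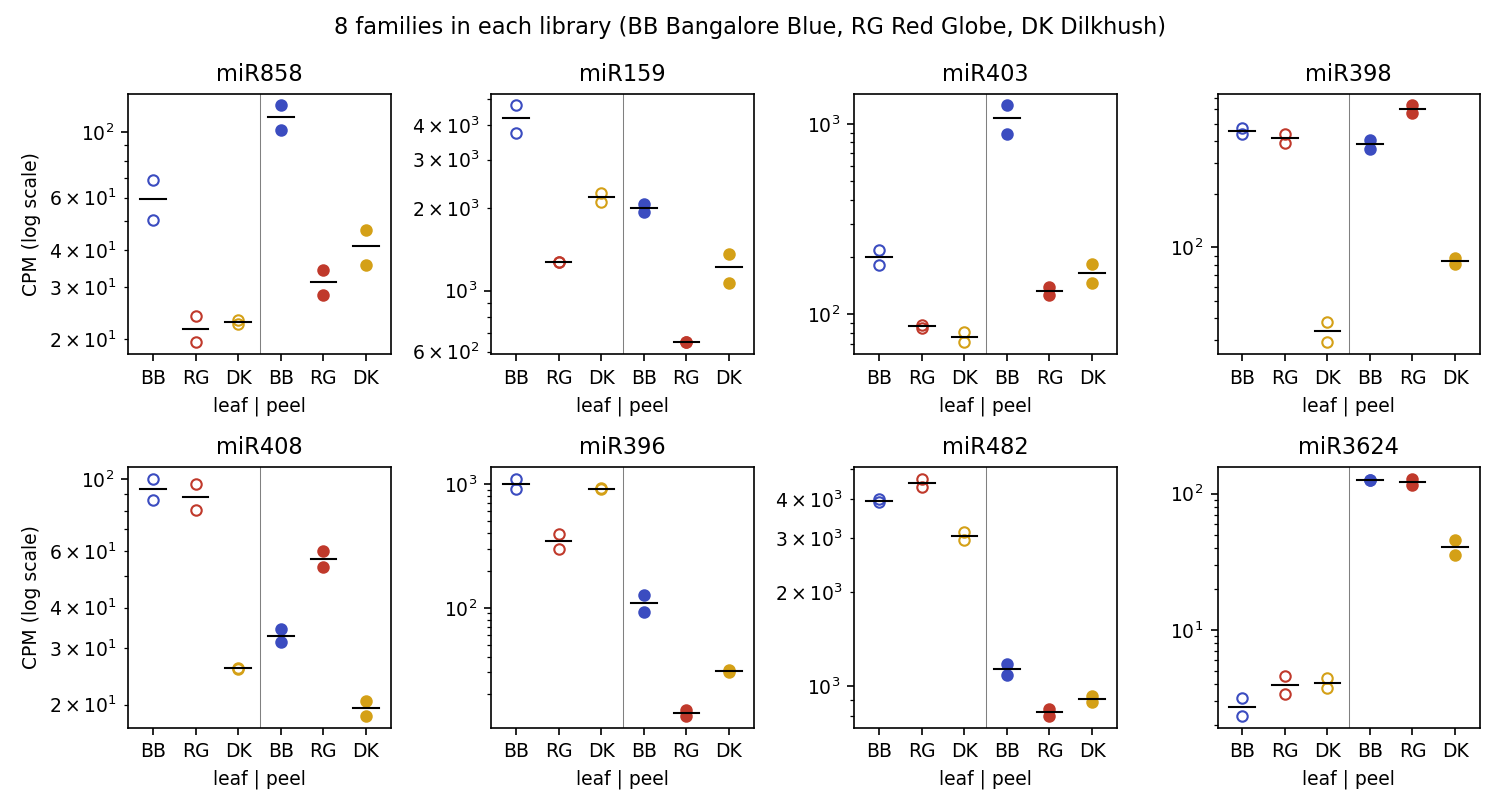
CPM on a log scale (vertical axis) of 8 families in the leaf (open points) and peel (filled points) libraries of each cultivar (horizontal axis), with group means as lines. For miR858, Bangalore Blue peel averaged 112 CPM against 31.2 in Red Globe and 41.1 in Dilkhush peel, and for miR398 Dilkhush stood lowest in both tissues, at 83.8 in peel and 33.6 in leaf. Scaled to miRNA reads, the peel against leaf direction of miR159 and miR408 and the higher miR482 of Bangalore Blue peel turn, with that of its leaf against Dilkhush, as do miR858, miR159, miR403 and miR396 between Bangalore Blue and Red Globe leaf, and miR159 between Red Globe and Dilkhush leaf. Between Red Globe and Dilkhush peel, miR858 and miR403 turn when scaled to miRNA or 24-nt reads, and miR159 when scaled to 24-nt reads.

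The same pairs were compared in leaf, a tissue with the same cultivar backgrounds. Bangalore Blue against Dilkhush in leaf gave 25 families higher and 2 lower of 35. The copper families were again higher, miR398 13.3-fold (3.73 ± 0.18), miR408 3.58-fold (1.84 ± 0.20) and miR397 with 33 against 0 reads (at least 7.61-fold). The phosphate-linked miR399 was 6.39-fold lower in Bangalore Blue (-2.68 ± 0.24), whereas miR2111 had 38 against 0 reads (at least 8.77-fold higher) and miR395 was 6.45-fold higher (2.69 ± 0.19). In leaf miR858 was 2.60-fold higher (1.38 ± 0.21, edgeR quasi-likelihood test, adjusted p = 9.3e-10), with 59.5 ± 12.7 against 22.8 ± 0.52 CPM.

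All 5 auxin families were higher, with miR390 at 2.32 ± 0.22 and tasiR-ARF at 2.04 ± 0.17, although miR167 and miR393 turned when scaled to miRNA reads. Both MYB-linked and all 3 copper families were higher. Of 8 development families 4 were higher, with miR319 at 2.11 ± 0.17 and miR394 at 2.01 ± 0.20, while miR171 turned when scaled to miRNA reads. Of 3 phase-change families 2 were higher, miR172 at 3.57 ± 0.59 and miR156, which turned when scaled to miRNA reads, and miR535 was 4.73-fold lower (-2.24 ± 0.40). Of 3 nutrient families 2 were higher and 1 lower, of 3 silencing families 2 were higher, and of 7 other families 4 were higher, with miR3634 at 2.13 ± 0.10 and miR479 at 2.18 ± 0.66. The NLR-targeting miR482 was higher, which turned when scaled to miRNA reads. The counts adjusted over the list alone were the same. Scaled to miRNA reads, miR482 passed in the opposite direction and the split was 14 and 9, with the median of 1.17 moved by -0.87 (without TMM it moved by 0.47). The call of miR479 was lost when scaled to miRNA reads (1.29) and without Dilkhush leaf replicate 2 (1.23) and reached 3.89 without its replicate 1, and miR172 reached 4.31 without Dilkhush leaf replicate 2.

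Red Globe against Dilkhush in leaf gave no difference in miR858 beyond the replicate spread (-0.09 ± 0.25, edgeR quasi-likelihood test, adjusted p = 0.781), which stood at 0.02 without TMM and 0.83 when scaled to miRNA reads. The copper families were higher in Red Globe, miR398 12.1-fold (3.601 ± 0.18), miR408 3.42-fold (1.77 ± 0.20) and miR397 with 7 against 0 reads (at least 2.46-fold). The largest fall was that of miR399, 38.5-fold lower (-5.27 ± 0.38), with 1.35 ± 1.31 against 48.0 ± 3.03 CPM, and miR395 was 5.03-fold lower (-2.33 ± 0.34).

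All 3 copper families were higher in Red Globe leaf, and of 3 nutrient families 2 were lower. Of 5 auxin families 2 were lower, miR160 at -1.61 ± 0.19 and miR167 at -1.16 ± 0.19. Of 3 phase-change families 2 were lower, miR535 at -1.25 ± 0.38 and miR156 at -0.98 ± 0.26. Of 8 development families 2 were higher, miR319 at 1.74 ± 0.17 and miR166 at 0.17 ± 0.05, which turned when scaled to 24-nt reads, and 2 were lower, miR396 at -1.40 ± 0.14 and miR169 at -1.97 ± 0.82. Of 3 silencing families miR168 was higher (0.53 ± 0.16) and miR162 lower (-0.82 ± 0.15), which turned to 0.08 when scaled to miRNA reads. Of the MYB-linked list miR159 was lower (-0.78 ± 0.12), which turned to 0.11 on that scale. Of 7 other families miR3627 was higher (2.29 ± 0.64) and miR3634 lower (-0.67 ± 0.09), which turned to 0.22 on that scale. The NLR-targeting miR482 was higher (0.57 ± 0.11). The counts adjusted over the list alone were the same.

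In all 8 families were higher and 11 lower in Red Globe leaf, or 14 and 4 when scaled to miRNA reads and 5 and 11 when scaled to 24-nt reads, with the median of -0.20 moved by 0.92 and -0.16 (without TMM by 0.12). Single libraries ended the calls of miR169 (-0.72 without Dilkhush leaf replicate 2, -1.59 and -2.71 without Red Globe leaf replicates 1 and 2), miR535 (-1.08 without Dilkhush leaf replicate 2), miR3627 (1.94 without Red Globe leaf replicate 2) and miR397 (without either Dilkhush leaf library or Red Globe leaf replicate 2). Without Red Globe leaf replicate 1 miR399 stood at -6.72, and without replicate 2 miR399 stood at -4.38 and miR395 at -3.33. Scaling to miRNA reads ended the calls of miR156 (-0.08), miR167 (-0.26), miR169 (-1.05) and miR535 (-0.33), and scaling to 24-nt reads those of miR168 (0.36) and miR482 (0.40). The calls of miR169 without TMM (-1.82) and with DESeq2 (-1.98), of miR166 without TMM (0.27) and of miR156 with exact mature sequences (-0.71) were also lost.

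Bangalore Blue against Red Globe in leaf gave 27 families higher and 2 lower, narrowly the most one-sided of the comparisons. With the replicate number as a block it gave 27 and 3, and Bangalore Blue against Dilkhush in leaf, at 25 and 2, was more one-sided. Bangalore Blue against Red Globe in leaf was also the comparison that depended most on the scaling. Scaled to miRNA reads, 3 were higher and 12 lower, with the median of 1.62 moved by -1.78 (without TMM by 0.36, and with DESeq2 by 0.12). That scale includes TMM factors among the families, which take out most of a shift shared by most families. The families that stayed higher on that scale and kept their call were miR395, miR3634 and miR160, at 3.22, 0.99 and 0.96, against 5.02 ± 0.26 (32.4-fold), 2.80 ± 0.10 (6.96-fold) and 2.77 ± 0.18 (6.80-fold) with TMM on all reads. The families miR3627, with 3 against 33 reads (16.8-fold, 5.27 to 85.6), and miR168 (-0.43 ± 0.16) were lower, and the call of miR168 was lost without TMM (-0.05) and when scaled to 24-nt reads (-0.32). For miR858 the difference was 1.46 ± 0.21 (edgeR quasi-likelihood test, adjusted p = 2.3e-10), which turned to -0.35 when scaled to miRNA reads.

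By list, all 5 auxin, 7 of 8 development, all 3 nutrient and both MYB-linked families were higher in Bangalore Blue leaf. Examples were miR167 at 1.9997 ± 0.18, miR390 at 1.89 ± 0.21, miR394 at 2.14 ± 0.21, miR169 at 2.06 ± 0.76, miR399 at 2.59 ± 0.54 and miR2111 with 38 against 3 reads (8.30-fold, 2.63 to 42.0). The phase-change list had 2 of 3 higher, with miR172 at 3.18 ± 0.57, the silencing list 2 higher and 1 lower of 3, the copper list 1 of 3 higher and the other families 5 higher and 1 lower of 7, with miR529 at 2.80 ± 0.61 and miR477 with 23 against 2 reads (7.53-fold, 1.86 to 65.9), while the NLR-targeting miR482 did not pass. Scaled to miRNA reads, 14 of the 29 called families turned: miR156, miR159, miR164, miR166, miR171, miR319, miR393, miR396, miR397, miR403, miR479, miR858, miR2950 and tasiR-ARF, of which miR164, miR166, miR171, miR319 and miR403 passed in the opposite direction. On that scale the calls of miR167 (0.20), miR169 (0.28), miR172 (1.39), miR390 (0.08), miR394 (0.34), miR399 (0.81), miR477 (1.07), miR529 (1.01) and miR2111 (1.21) were lost. Adjusted over the list alone the counts were the same, except that 1 phase-change family was lower. Single libraries ended the calls of miR168 and miR169 (-0.41 and 1.69 without Bangalore Blue leaf replicate 1, -0.34 and 1.68 without Red Globe leaf replicate 1) and of miR477 (2.07 without Red Globe leaf replicate 1, fitted 6.83 without its replicate 2), and miR2111 was fitted at 3.74 and 2.37 without these libraries. Without Red Globe leaf replicate 1 miR399 stood at 4.05, and without replicate 2 miR399 stood at 1.71, miR395 at 6.02 and miR169 at 2.80.

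Whether a cultivar difference in peel differed from that in leaf was tested by the interaction terms. For miR858 none passed (0.08 ± 0.27, -0.31 ± 0.31 and 0.38 ± 0.28 for Bangalore Blue against Dilkhush, Red Globe against Dilkhush and Bangalore Blue against Red Globe, edgeR quasi-likelihood test, adjusted p = 0.774, 0.473 and 0.248). The Bangalore Blue against Dilkhush value turned to -0.36 without TMM, that of Red Globe against Dilkhush to 0.87 when scaled to 24-nt reads, and that of Bangalore Blue against Red Globe to -0.27 and -0.30 on those scales. Scaled to miRNA reads, both values that involve Bangalore Blue passed, at 0.65 and 1.30. For Bangalore Blue against Dilkhush 7 families had a larger and 14 a smaller value in peel (12 and 8 when scaled to miRNA reads, 9 and 6 when scaled to 24-nt reads). The phase-change family miR535 was higher in Bangalore Blue peel and lower in its leaf, with an interaction of 4.09 ± 0.49, and miR395 showed the reverse, with -4.58 ± 0.35, while miR3634 (-2.12 ± 0.13) was higher in Bangalore Blue leaf only. For Red Globe against Dilkhush 6 were larger and 7 smaller (6 and 3 without TMM, 5 and 10 when scaled to miRNA reads, 17 and 1 when scaled to 24-nt reads), with miR319 at -2.73 ± 0.23 and miR399 at 4.04 ± 0.67, which was 5.50 and 3.16 without Red Globe leaf replicates 1 and 2. For Bangalore Blue against Red Globe 7 were larger and 11 smaller (5 and 14 without TMM, 13 and 6 when scaled to miRNA reads, 5 and 14 when scaled to 24-nt reads), with miR403 at 1.80 ± 0.22 and miR319 at 2.01 ± 0.22. All 3 copper families had smaller values in peel for Bangalore Blue against Dilkhush and against Red Globe, of which miR398 and miR408 turned in the latter when scaled to miRNA reads, while on that scale the calls of miR408 (-0.52) and miR397 in the former and of miR397 (-1.64) in the latter were lost. The median interaction moved by -0.44, 0.22 and -0.63 in the 3 pairs without TMM, by 0.59, -0.32 and 0.90 when scaled to miRNA reads and by 0.49, 1.18 and -0.64 when scaled to 24-nt reads. The interaction values of the families selected by the naming rule, and the alternatives and libraries that ended them, are given in the closing section. Adjusted over the list alone, Bangalore Blue against Red Globe had 1 rather than 2 of the other families smaller, and Red Globe against Dilkhush had 1 larger and 2 smaller phase-change families and 2 smaller silencing families.

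Tests on single sequences of 20 to 24 nt asked how far the populations differed beyond the listed families. Between tissues, 4154 sequences were higher and 4036 lower in peel of 18127 tested (6946 and 2722 without TMM, 2777 and 3689 with DESeq2). The leading sequence in peel was TTTGGACTGAAGGGAGCTCCT of miR319, which targets TCP factors. It reached 433, 79.7 and 165 CPM in Bangalore Blue, Red Globe and Dilkhush peel, with 3917, 839 and 1667 reads, against 0, 2 and 1 reads in the leaf groups. The family as a whole differed less between tissues (0.40), with other miR319 sequences present in leaf. That value averages opposite directions. The family was higher in peel than in leaf in Bangalore Blue (484 against 273 CPM) and Dilkhush (185 against 63.4), but lower in Red Globe (92.9 against 211). In peel, Bangalore Blue against Dilkhush gave 4148 higher and 4456 lower sequences (4308 and 4222 without TMM). Red Globe against Dilkhush gave 3224 and 4752 (4165 and 3584 without TMM). Bangalore Blue against Red Globe gave 5433 and 4784 (4732 and 5464 without TMM, 2809 and 2866 with DESeq2). In leaf the pairs in the order above gave 3777 and 3525 (5244 and 2596 without TMM, 1664 and 1793 with DESeq2), 2598 and 1944, and 4026 and 4284 (5163 and 3567 without TMM). Small majorities of sequences thus depended on the setting.

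Among the called 24-nt sequences, 39.0% were higher in Bangalore Blue than in Dilkhush peel and 31.3% were higher in Red Globe than in Dilkhush peel. With 24-nt sequences tested and scaled alone the splits were more even, 1086 higher and 1326 lower for the former pair and 986 and 1205 for the latter. Of the 21-nt sequences, 67.4% of those called between Bangalore Blue and Dilkhush leaf were higher in Bangalore Blue, and with 21-nt and 22-nt sequences tested and scaled alone 2232 were higher and 1866 lower. Sequences called for a cultivar pair overlapped between peel and leaf, which are separate libraries. For Bangalore Blue against Dilkhush 1993 sequences were higher in both tissues, where independent lists would share 864, and 1522 were lower in both, where independent lists would share 867. For Bangalore Blue against Red Globe 2308 were higher in both against 1207 expected, and for Red Globe against Dilkhush 731 against 462. Sequences lower in both numbered 2015 against 1131 expected and 876 against 510 in these pairs. In the opposite direction in leaf were 226 and 266 of the sequences higher and lower in peel for Bangalore Blue against Dilkhush (807 and 928 expected), 584 and 363 for Bangalore Blue against Red Globe (1284 and 1063 expected) and 398 and 620 for Red Globe against Dilkhush (346 and 681 expected). Among families, 14 were higher in both tissues for Bangalore Blue against Dilkhush (14.3 expected), 16 for Bangalore Blue against Red Globe (15.4 expected) and 5 for Red Globe against Dilkhush (1.6 expected). Their fold changes in peel and leaf had Pearson correlations of -0.210, 0.0879 and 0.454. Of the 18127 sequences tested, 1079 shared at least 15 bases with circular sequences found in the reads, though not all of them lay on a circle in full. Among sequences called with over 64-fold changes in peel, 528 of 3021 shared such bases for Bangalore Blue against Dilkhush. The numbers were 89 of 1390 for Red Globe against Dilkhush and 433 of 2618 for Bangalore Blue against Red Globe. In leaf the same pairs gave 168 of 1859, 341 of 1227 and 561 of 2386, and peel against leaf gave 0 of 197. The naming rule made 41 other selections over the comparisons, in which some sequences came up more than once. None belonged to a listed family, some shared at least 15 bases with the circular sequences, and their origin was not assigned.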

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

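The search for circular RNAs and the tests of the leaf shift were chosen after the results were seen, whereas the prediction for sequence variants was written before its value was seen, and the read set and overlap of the circle search were widened after its first form closed no circle.

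Interaction values set a cultivar difference in peel against that in leaf, and those of the families selected by the naming rule that passed the threshold were as follows (edgeR quasi-likelihood test). For Bangalore Blue against Dilkhush the peel value was larger for miR530 (6.66), miR535 (4.09), miR3627 (3.09), miR399 (2.64), miR3624 (2.22), miR396 (1.72) and miR403 (1.30). It was smaller for miR395 (-4.58), miR160 (-4.31), miR479 (-3.58), miR169 (-2.67), miR172 (-2.51), miR3634 (-2.12), miR398 (-1.54), miR171 (-1.47), miR408 (-1.10) and miR167 (-0.99). With a group at 0 reads, miR2111 (adjusted p = 1.1e-07) and miR397 (adjusted p = 0.0309) were also smaller (edgeR quasi-likelihood test). Outside that selection miR166 (-0.80) and miR319 (-0.72) passed as well. Single libraries ended the calls of miR3627 (2.53 to 3.50 in 6 of the fits), miR397 and miR169 (-2.30 without Bangalore Blue leaf replicate 1, -2.41 without Bangalore Blue peel replicate 2), and moved others by over 1.5 times: miR530 (5.59 to 10.63), miR479 (-2.64 to -5.30), miR160 (-3.58 to -6.35) and, without Dilkhush leaf replicate 2, miR169 (-3.92) and miR172 (-3.25). Scaling to 24-nt reads ended the calls of miR167 (-0.46), miR169 (-2.18), miR171 (-0.99), miR172 (-1.98), miR397 and miR408 (-0.59), and scaling to miRNA reads those of miR167 (-0.40), miR171 (-0.91), miR397 and miR408 (-0.52). The calls of miR396 (0.16) and miR171 (-0.60) were lost with 1 mismatch, those of miR167 (-0.71), miR172 (-2.07) and miR530 (5.19) with exact mature sequences, that of miR3627 without TMM (2.70), and those of miR397 and miR3627 (3.09) with only the libraries compared. The values of miR160, miR530 and miR3627 rest on a group with 1 to 3 reads.

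For Red Globe against Dilkhush the peel value was larger for miR530 (4.58), miR399 (4.04), miR169 (2.74), miR3624 (1.66), miR167 (1.21) and miR166 (0.39). It was smaller for miR319 (-2.73), miR171 (-1.60), miR168 (-1.28) and, with Red Globe peel at 0 reads, tasiR-ARF (edgeR quasi-likelihood test, adjusted p = 0.0217). It was also smaller for miR156 (-0.98), miR398 (-0.75) and miR482 (-0.71), all of which turned when scaled to 24-nt reads. Single libraries ended the calls of miR156 (-0.57 to -1.03 in 6 of the fits), miR530 (3.87 to 7.68 in 7), miR169 (1.495 to 3.48 in 4), miR3624 (1.44 and 1.53 without leaf replicate 2 of Red Globe or of Dilkhush), miR398 (-0.59 without Dilkhush leaf replicate 1, -0.68 without Red Globe peel replicate 2) and tasiR-ARF, while miR399 moved to 5.496 and 3.16 without Red Globe leaf replicates 1 and 2 and miR530 to 7.23 without Dilkhush peel replicate 2. Scaling to 24-nt reads also ended the calls of miR168 (-0.08), miR171 (-0.46) and tasiR-ARF, and scaling to miRNA reads that of miR166 (0.07). Without TMM the calls of miR156 (-0.77), miR171 (-1.39), miR398 (-0.54) and miR482 (-0.49) were lost, with exact mature sequences those of miR171 (-1.07) and miR530 (4.61), and that of miR156 with DESeq2 (-0.92) and with only the libraries compared (-0.98). The value of miR530 rests on groups with 1 and 2 reads.

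In the pair Bangalore Blue and Red Globe the peel value was larger for miR535 (3.02), miR319 (2.01), miR403 (1.80), miR168 (1.68), miR396 (1.45), miR156 (1.11) and miR482 (0.65), the last of which turned when scaled to 24-nt reads. It was smaller for miR2111 (-6.24), miR169 (-5.41), miR160 (-5.40), miR395 (-3.73), miR397 (-2.52), miR167 (-2.19), miR3634 (-2.11) and miR166 (-1.19). It was also smaller for miR408 (-0.85) and miR398 (-0.79), both of which turned when scaled to miRNA reads. Outside the selection miR2950 (-1.87) passed as well. Single libraries ended the calls of miR397 (-1.94 to -2.36 in 3 of the fits) and miR156 (0.71 without Red Globe leaf replicate 2, 1.04 without Red Globe peel replicate 1), and moved others by over 1.5 times: miR160 (-4.78 to -7.44), miR2111 (-5.60 to -6.98) and, without Red Globe leaf replicate 2, miR169 (-6.15), miR395 (-4.73) and miR397 (-4.04). The calls of miR156 (0.46) and miR482 (0.00078) were lost without TMM, that of miR156 when scaled to 24-nt reads (0.43), those of miR166 (-0.28) and miR397 (-1.64) when scaled to miRNA reads and that of miR396 with 1 mismatch (0.28). The values of miR160 and miR2111 rest on a group with 1 to 3 reads.

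Reads matching hop stunt viroid reached 0.520% of a library. Animal let-7 reached 318 reads and animal miR-21 reached 367 reads in a library. Reads sharing 15 bases with the circular sequences reached 1.87% in Dilkhush peel replicate 1.

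Of the sequences with at least 100 reads, 1843 were missing from all 4 libraries of a cultivar or of 2 (at most 3 reads there): 1109 from Bangalore Blue, 883 from Red Globe and 602 from Dilkhush, or 2594 pairs of a sequence and a cultivar. A variant of the same sequence in that cultivar may account for some, but 10.5% of these pairs (272 of 2594) had a partner with 1 substitution against 14.8% of shared sequences, so this stayed undecided. A circular infectious RNA could account for another part. Of the missing sequences, 17.04% (314 of 1843) lay on closed circles against 2.07% of shared sequences. The search started from missing sequences, so this excess is partly set by its design and cannot decide the question. The share on circles was 27.3% for sequences missing from Bangalore Blue, 1.16% for Dilkhush and 1.13% for Red Globe. The circles found would thus concern mainly Bangalore Blue, and the explanation stayed undecided. Circles of 372, 299 and 363 nt were closed, and their reads were pooled over leaf and peel of a cultivar. Reads on the first and last were near-absent from Bangalore Blue, at 0.567 and 1.56 RPM. They stood at 3812 and 4088 in Dilkhush and at 2764 and 6503 in Red Globe. Those on the 299-nt circle were most frequent in Bangalore Blue, at 6910 against 2254 in Dilkhush and 1836 in Red Globe. The pooled values hide a tissue difference: reads sharing 15 bases with any circle made up 0.301% and 0.276% of the Dilkhush leaf libraries and 1.87% and 1.58% of its peel libraries. Single circles were not counted by tissue.

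In leaf, miRNA families lay higher in Bangalore Blue than in Red Globe, with a median log2 fold change of 1.62. Dilution of all small RNAs of Red Globe by reads of other kinds could give such a shift, but scaled to 24-nt reads the median was 1.71, which argues against it. The share of miR166 alone could not give it either, since without miR166 the reads in families were at least 3.33 times as frequent in every Bangalore Blue leaf library, a ratio that fell to 1.76 without miR3634 as well. For a shift of all 21-nt reads, the median over unlisted 21-nt sequences was 0.22. The TMM factors came from the same sequences and hold that median near 0, so it cannot decide this. The 21-nt share of reads was 44.3% in Bangalore Blue leaf and 28.7% in Red Globe leaf, and the question stayed undecided. A difference in miRNA abundance between the cultivars, or in leaf stage at sampling, remains possible and was not tested. Signs of RNA breakdown were mixed. Reads matching 5.8S ribosomal RNA made up 0.694% of Red Globe leaf and 0.299% of Bangalore Blue leaf, whereas the 5' end of tRNA-Ala made up 0.049% and 0.086%. Their link to the shift was not tested.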

How the results depend on the processing

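Of the values of named families under the other alternatives, 1573 kept their direction and their place above or below the threshold. A further 94 kept the direction but lost the call, 2 gained one and 24 reversed. These counts do not measure how far a value moved. With each library left out 4 values reversed and the rest kept their direction, and the calls that single libraries ended are given above. Some values moved far, such as miR477 for Bangalore Blue against Red Globe in leaf, from 2.83 to 6.83 without Red Globe leaf replicate 2. The counts of families stayed within 1.5 times in 98 of 99 alternatives and in 59 of 60 fits with a library left out. With a library left out, called families ranged over 24 to 26 for peel against leaf, 22 to 24, 19 to 23 and 24 to 26 for Bangalore Blue against Dilkhush, Red Globe against Dilkhush and Bangalore Blue against Red Globe in peel, 25 to 26, 16 to 20 and 22 to 28 for the same pairs in leaf, and 17 to 21, 8 to 13 and 16 to 19 for their interactions. The lowest, 8 against 13 for the Red Globe against Dilkhush interaction, came without Red Globe peel replicate 2, and the cause was not tested. Called sequences with a library left out ranged over 7557 to 8145 for the tissues, 7300 to 7984, 6622 to 7103 and 8849 to 9391 in peel and 5419 to 6099, 3123 to 3474 and 6503 to 7160 in leaf. The 21-nt difference ranged from 0.16 to 1.80 points and the 24-nt difference from 1.72 to 2.23.

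Without TMM, miR858 turned to 0.0237 for Red Globe against Dilkhush in leaf and to -0.36 and -0.27 for the interactions of Bangalore Blue against Dilkhush and against Red Globe. Scaled to miRNA reads, miR156 turned to 0.0615 for peel against leaf, miR858 to 0.18 for Red Globe against Dilkhush in peel, 0.83 for the same pair in leaf and -0.35 for Bangalore Blue against Red Globe in leaf. On that scale miR162, miR159 and miR3634 turned to 0.0778, 0.11 and 0.22 for Red Globe against Dilkhush in leaf, and miR408 and miR398 to 0.0551 and 0.13 for the Bangalore Blue against Red Globe interaction. Scaled to 24-nt reads, miR858, miR319, miR159 and miR162 turned to 0.62, 0.00769, 0.10 and 0.18 for Red Globe against Dilkhush in peel, and miR166 to -0.0022 in leaf. On that scale miR858, miR156, miR398 and miR482 turned to 0.87, 0.18, 0.42 and 0.47 for the Red Globe against Dilkhush interaction, and miR858 and miR482 to -0.30 and -0.0278 for that of Bangalore Blue against Red Globe. With 1 mismatch, miR479 turned to 0.25 for Bangalore Blue against Dilkhush in peel. With a library left out, miR858 turned to -0.13, -0.06 and -0.12 for the Bangalore Blue against Dilkhush interaction without Bangalore Blue leaf replicate 2, Bangalore Blue peel replicate 1 and Dilkhush peel replicate 2 (range up to 0.31, without Bangalore Blue leaf replicate 1), and to 0.0688 for Red Globe against Dilkhush in leaf without Red Globe leaf replicate 2 (range down to -0.22, without its replicate 1). For these reversals the cause was not tested.

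Scaled to miRNA reads, 15 families were called for Bangalore Blue against Red Globe in leaf against 29, and the cause was not tested. As a share of reads of 20 to 24 nt the 24-nt difference was 4.01 points against 1.98, and over distinct sequences -4.88, and the cause was not tested. In the order Bangalore Blue against Dilkhush, Red Globe against Dilkhush and Bangalore Blue against Red Globe, in peel then leaf, distinct sequences past the threshold numbered 8604, 7976, 10217, 7302, 4542 and 8310, and with DESeq2 distinct sequences numbered 4011, 3319, 5675, 3457, 1947 and 4473, for which the cause was not tested. Fewer sequences were tested under the next settings, which lowers the counts. Starting with peel against leaf (8190), distinct sequences numbered 3838, 3748, 3743, 4540, 3423, 2467 and 3734 with the stricter filter (6669 tested), 1650, 2412, 2191, 2659, 1918, 1515 and 2289 for 24 nt alone (4501 tested) and 4282, 4898, 4301, 5619, 4098, 2246 and 4503 for 21 and 22 nt (9502 tested).

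The replicate numbers did not pair libraries across groups, with correlations of -0.0507 to 0.119 over 15 pairs of groups. With the number as a block, called miRNA families were 26, 24, 24, 26, 27, 19 and 30, with 20, 12 and 18 for the interactions, and distinct sequences 8360, 8860, 8210, 10398, 7496, 4835 and 8437. Exact permutation p-values of the 21-nt and 24-nt shares were 0.844 and 0.3125 (smallest possible 0.0313). The block ended the calls of miR397 for Bangalore Blue against Dilkhush in peel, of miR3627 for that interaction and of miR156 and miR530 for the Red Globe against Dilkhush interaction. It changed no other call of the families selected by the naming rule, but added 1 lower family each for Bangalore Blue against Red Globe in leaf and for the Red Globe against Dilkhush interaction. Without sequences that shared 15 bases with the circles, all 173 values of named families kept their direction and call. The split of the Red Globe against Dilkhush interaction was then 6 and 8, against 6 and 7. The alternative restricted to sequences matching a genome and the result on small RNAs at MYB genes were not run.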

Other observations

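Small RNAs of 21 nt began with U, the base preferred by the miRNA-binding AGO1 protein, in 69.9% ± 0.42 of reads in Bangalore Blue leaf, 62.3% ± 0.32 in Bangalore Blue peel, 61.8% ± 0.70 in Red Globe peel, 50.8% ± 0.43 in Dilkhush leaf, 49.5% ± 1.15 in Dilkhush peel and 44.4% ± 1.82 in Red Globe leaf (SD, n = 2). These shares partly reflect miR166, whose main sequences begin with U. It made up 22.8% and 19.9% of all reads in the Bangalore Blue leaf libraries and 6.96% and 8.24% in those of Red Globe leaf. Shares of U without miR166 were not computed. Reads of 24 nt began with A, the base preferred by AGO4-type proteins, in 31.1% to 42.1% of reads of each group. The main miR403 sequence, TTAGATTCACGCACAAACTCG, had 14562 reads, and miR403 reached 1070 ± 258 CPM in Bangalore Blue peel against 75.9 to 200 CPM in the leaf groups.

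The comparisons of other splits of the libraries were planned after the result was seen. Of 100 splits of the 12 libraries into 6 and 6, only the real tissue split gave as many families past the threshold, 16, where the highest other split gave 2. In the same 100 splits only 1, the real one, gave as many sequences, 3859, where the highest other split gave 101. The fits of the splits thus called fewer features than the main peel against leaf fit, with 26 families and 8190 sequences, so they do not examine those numbers directly. Nearly all of these splits part the replicates of a group, which may be technical, so they are no fair measure of chance. Of the 10 splits that keep every group whole, the highest other gave 3 families and 2481 sequences, and 10 splits are too few for a share under 0.05.

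The miRNA level most directly tied to the title, that of miR858, had no fixed place in the colour order of the berries. In peel it was highest in Bangalore Blue under every scaling, but Red Globe against Dilkhush was -0.39 with TMM, 0.18 when scaled to miRNA reads and 0.62 when scaled to 24-nt reads, and only the first and last of these passed the threshold, in opposite directions. In leaf it was highest in Bangalore Blue as well, but the difference from Red Globe turned to -0.35 when scaled to miRNA reads. In leaf the Red Globe against Dilkhush value was 0.02 without TMM and 0.83 when scaled to miRNA reads, so a moderate difference between these cultivars may have gone undetected. Levels of target mRNAs and of anthocyanin would be needed to relate miR858 to colour, and neither was analysed here. The copper families miR398 and miR408, which were lower in Dilkhush than in both other cultivars in both tissues, could differ through copper supply as well as genotype. Against Dilkhush leaf, the log2 fold change of miR398 was 3.73 in Bangalore Blue leaf and 3.601 in Red Globe leaf. Both comparisons share the Dilkhush libraries, so they count as a single observation.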
